A study of Columba livia with 7 samples.

How the data were processed

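Small RNA from exosomes of pigeon milk (Columba livia) was sequenced in 7 libraries from 5 stages. Per the labels these were day 1, with 3 replicates, and days 5, 10, 15 and 20, with 1 library each. The labels do not say whether the day 1 replicates came from separate birds, pools or preparations. All p-values therefore measure only the spread between these samples, which may be technical.

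The authors gave the abundance of each miRNA as RPM, the reads of that miRNA scaled to a fixed library total. Their processing notes name Bowtie without a version; the genome build, the annotation and the counting rule were not given in the sources used here. Each file listed the same 301 entries, 248 of them named conserved by the authors and 53 not. The non-conserved entries are described below by their values, without their deposited names. The values of the sample files and of the series table differed by at most 0.

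Every value was a whole multiple of its library's smallest step, within a tolerance of 0.001 read (largest distance 4.31e-05). The step gave the number of reads behind each value and the library total that the authors divided by. The listed entries held only part of that total. Shares of reads carry 95% exact binomial confidence intervals. The floor was 3 reads per library, and a fold against a group at 0 in every library was computed against that floor as a lower bound. For day 1 the highest floor of its 3 libraries was used. Intervals and floors cover counting error only.

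A count test was the first choice and limma on log2(RPM + 1) the choice for normalized values, both set before the data were examined. Count tests on the recovered reads were left out, although every value was whole: each library had 66 to 86 values of up to 20 reads, under the 100 set as the minimum for treating the reads as recovered. limma was used. Values were analysed as log2(RPM + 1), with eBayes and trend = TRUE, two-sided. Entries with a mean of at least 10 reads were tested, and p-values were adjusted by Benjamini-Hochberg over them with a threshold of 0.05. Where both sides have reads, the pseudocount makes log2 changes of rare miRNAs smaller than the ratio of their RPM. At days 15 and 20, 1 read was worth 5.05 and 3.50 RPM. A log2 change to a listed 0 there can therefore exceed the lower bound that the floor gives.

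The comparisons were days 5 to 20 against day 1, a trend per day over all 7 libraries, a trend over the 4 later libraries, and each later day against day 1. The comparisons by day came from 1 model with a term per stage. Its spread came from the 3 day 1 libraries alone, with 2 residual degrees of freedom, so a lone later library was assumed to vary like day 1. A miRNA listed at 0 in every day 1 library showed little spread there, and its standard error is small for that reason. The 4 comparisons by day share the day 1 libraries and are not independent of each other.

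The miRNA lists were fixed before the data were examined, as were the alternatives except those named in the closing section. They were the let-7, miR-200, miR-30 and miR-10/99/100 families, the miR-17-92 clusters, other epithelial miRNAs, immune regulators, lipid metabolism, miRNAs abundant in mammalian milk, hypoxia, and miRNAs of red blood cells, leukocytes, muscle, neurons, endothelium, liver, gut, and fibroblasts and matrix. Several miRNAs stand in more than 1 list. Members past the threshold were counted with adjustment over all tested entries and over the list alone. The limma function camera compared a list with the other miRNAs with a preset correlation of 0.01, and again with an estimated correlation. The function fry tested whether the members moved, on balance, one way. It does not compare a list with the other miRNAs, so a shift of most miRNAs one way can make it pass. Because camera is relative to the other miRNAs, its direction can be opposite to the sign of a list's median.

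miRNAs were named by a rule fixed in advance. It took the 10 with the highest mean RPM at day 1 and any other among the 10 highest at the later days. It took up to 8 passing miRNAs in each direction for the comparison of later days and for the trend, with a mean of at least 10 RPM, and up to 3 in each direction for each later day. It took 2 to 4 members of each list by mean RPM. Where fewer than 5 passed, the 5 with the smallest p are given as values. Outside the rule, miR-17-5p, miR-18b-5p, miR-30a-3p, miR-30e-3p, miR-98-5p, miR-99a-5p, miR-200b-5p, miR-222a-3p and miR-1229-1-3p were chosen after their values were seen. So were the further miRNAs named in the closing section.

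The alternatives were median-of-ratios scaling, listed-read scaling (each library divided by its listed miRNA reads instead of its whole total), a pseudocount of 10, no filter or a mean of at least 100 reads, members of a family and arm summed, and leaving out each library. Scaling to equal listed totals, which is listed-read scaling with values kept near their deposited size, summing both arms of a hairpin, thinning to a denominator of 198210 reads and other alternatives given in the closing section were added later. Composition measures were compared by exact permutation over the 35 splits of 3 against 4 libraries and by exact permutation of the day over 5040 orders, two-sided, with adjustment over 9 measures.

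The work used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The comparison of days 5 to 20 with day 1 was also run on simulated data, with noise set from the day 1 spread. It recovered 0.85% of log2 changes of 1, 23.8% of those of 2 and 91.0% of those of 4. Most changes of a log2 of 2 or less would therefore be missed. Stages that move in opposite directions were not simulated. The simulated noise had the same SD for every miRNA (0.88 in log2). It held no differences between the later stages, which enter the spread of the real comparison. The percentages can therefore be too high for miRNAs that differ between the later stages. In the real comparison, log2 changes larger than 4 in size also did not all pass, as given below. No entry was joined to a genome position, and no sequence was analysed here.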

Results

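Pigeon milk is the secretion of the crop that parent pigeons feed to their squabs, and exosomes are small vesicles that carry RNA between cells. The series asked how the miRNA profile of milk exosomes differs across 5 stages. Day 1 had 3 libraries, and days 5, 10, 15 and 20 had 1 each, so no later day has replicates. The labels do not say from what event the days were counted. The authors' files listed 301 miRNA entries per library as RPM.

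The listed miRNAs held 82000, 171825 and 156600 reads in day 1 replicates 1, 2 and 3. They held 82944 reads at day 5, 35559 at day 10, 6564 at day 15 and 3620 at day 20. As a share of the reads that the RPM values were divided by, this was 5.27% (95% interval 5.24 to 5.31), 6.13% (6.10 to 6.15) and 3.79% (3.77 to 3.81) at day 1. The share was 17.7% (17.6 to 17.8) at day 5 and 10.2% (10.1 to 10.3) at day 10. It was 3.31% (3.23 to 3.39) at day 15 and 1.27% (1.23 to 1.31) at day 20. The floor of 3 reads lay between 0.726 and 1.93 RPM in the day 1 libraries, and at 6.40, 8.63, 15.1 and 10.5 RPM at days 5, 10, 15 and 20. At days 15 and 20 a miRNA below the floor was not detectable at this depth.

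**Figure D1:**
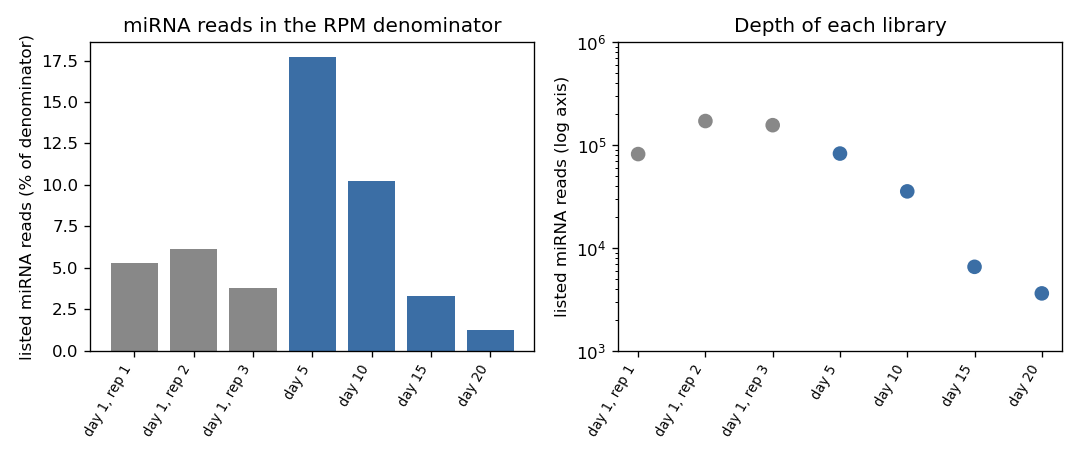
Listed miRNA reads in the 7 libraries, day 1 in grey and later days in blue: bars on the left give their percent of the reads used as the RPM denominator, and points on the right give their number on a log axis. The share was highest at day 5 (17.7%) and lowest at day 20 (1.27%), and the number was lowest at day 20 (3620 reads).

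miR-21-5p, a widely expressed miRNA that targets tumour suppressor transcripts, was the most abundant miRNA at day 1, at 9136 ± 1424 RPM (SD, n = 3). miR-148a-3p, among the most abundant miRNAs of mammalian milk, stood at 4406 ± 2032 RPM. The Hox-cluster miRNA miR-10a-5p stood at 3987 ± 1865 RPM and miR-26a-5p at 3606 ± 571 RPM. miR-146c-5p was at 3376 ± 3032 RPM and miR-146b-5p, whose family dampens Toll-like receptor signalling, at 2663 ± 1359.9 RPM. miR-205a-5p, of a family typical of stratified epithelia, was at 2659 ± 1394 RPM. Of the other entries among the 10 highest at day 1, miR-877-5p was listed at 6738 and 841 RPM in replicates 1 and 2 and at 0 in the remaining libraries. Another was non-conserved and had 5763 RPM in day 1 replicate 2 alone. The correlations between day 1 replicates across miRNAs, which are not independent of each other, were 0.40 (1 and 2), 0.52 (1 and 3) and 0.69 (2 and 3). Replicate 3 had higher correlations with day 5 (0.72) and day 10 (0.75) than with the other day 1 replicates.

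At day 5 miR-148a-3p and miR-21-5p had 35883 and 35644 RPM, and miR-205a-5p had 16281 RPM. At day 10 miR-148a-3p was highest at 13776 RPM, with miR-22-3p at 12398 and miR-205a-5p at 8753 RPM. miR-92-3p, of the miR-17-92 clusters, went from 841 ± 297 RPM at day 1 to 6209 RPM in the day 10 library, a value without replicates. At day 15 miR-215-5p was highest at 6498 RPM, and miR-21-5p had 1549 RPM. At day 20 miR-1229-1-3p was highest at 1675 RPM, against 3.86, 2.85 and 0 RPM in the day 1 replicates. A non-conserved entry had 1486 RPM in that library, miR-205a-5p 1168 RPM and miR-21-5p 755 RPM. The miRNAs abundant in mammalian milk, taken as a list, held 48.0, 53.3 and 69.1% of listed reads in the day 1 replicates. They held 60.6% at day 5, 58.3% at day 10, 15.8% at day 15 and 20.6% at day 20.

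**Figure D2:**
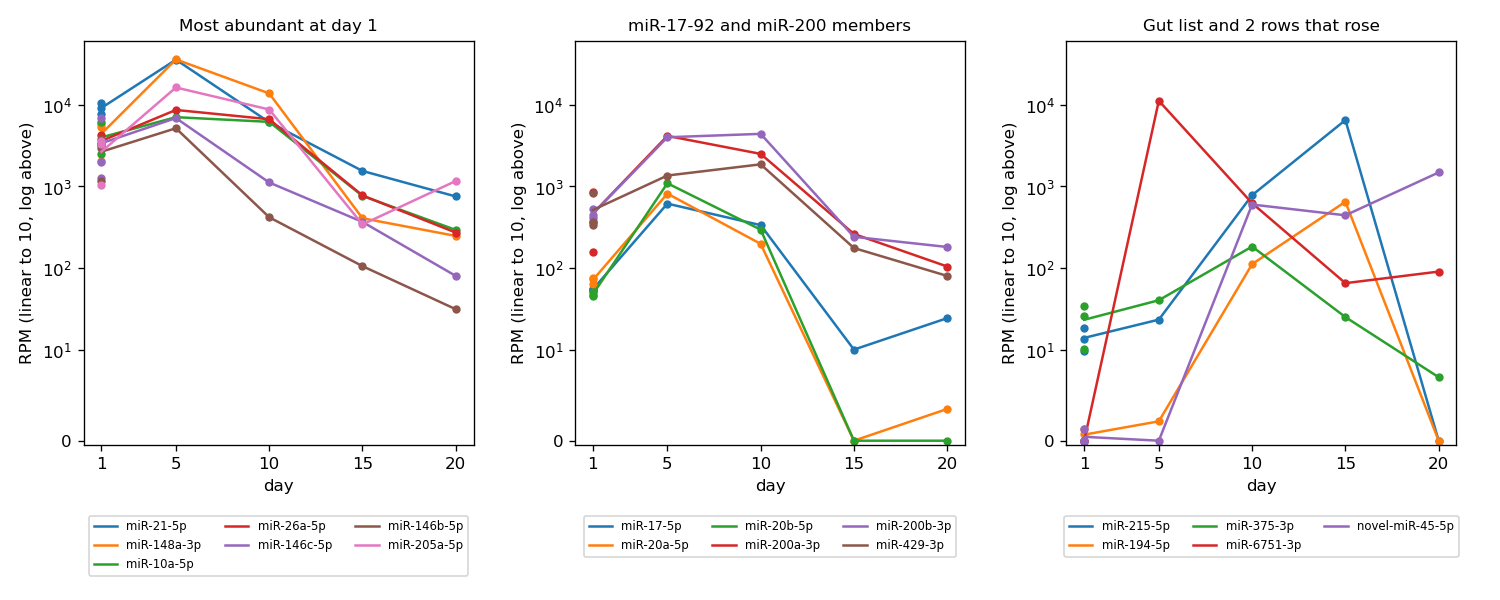
RPM of named miRNAs in each library against day (axis linear to 10 RPM, logarithmic above), with points for libraries and lines through the day 1 mean and the later libraries; the panels hold abundant miRNAs of day 1, members of the miR-17-92 clusters and the miR-200 family (miR-17-5p chosen after its values were seen), and the gut list with 2 entries that rose. miR-20b-5p peaked at day 5 (1095 RPM) and was at 0 on days 15 and 20, and miR-215-5p peaked at day 15 (6498 RPM).

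The first comparison asked which miRNAs differed between the 4 later libraries and the 3 day 1 libraries. miR-6751-3p was listed at 0 in every day 1 library and rose in the later ones, to 11194 RPM (5243 reads) at day 5, 624 RPM at day 10, 65.6 RPM at day 15 and 90.9 RPM at day 20. These were at least 5804-, 324-, 34.0- and 47.1-fold above the day 1 floor, and the miRNA was higher in 4 of 4 later libraries. It was the 1 miRNA of 158 tested to pass (limma log2 change 8.83, SE 2.03, Benjamini-Hochberg adjusted p = 0.00252), and 8 had an unadjusted p under 0.05. The next smallest p belonged to miR-877-5p (log2 change -7.48, limma adjusted p = 0.133), a non-conserved entry (6.75, adjusted p = 0.133), miR-3178-5p (-6.54, adjusted p = 0.353) and another non-conserved entry (5.79, adjusted p = 0.517). None of those 4 passed. No member of any list passed in this comparison. The smallest camera p was that of the gut list, 0.0478, with an adjusted p of 0.669, and no list had an adjusted p under 0.978 with an estimated correlation. The median log2 change of all tested miRNAs was -0.55 as deposited, -0.68 with median-of-ratios scaling and -1.02 with listed-read scaling. The call depended on single libraries and on the pseudocount: miR-6751-3p had an adjusted p of 0.179 without day 1 replicate 3 and of 0.0793 without day 5, and of 0.342 with a pseudocount of 10. Without day 1 replicate 3, miR-877-5p and miR-3178-5p passed instead (adjusted p = 0.0387 and 0.0456), and without day 5 a non-conserved entry did. With days 15 and 20 left out, an alternative added later, 7 miRNAs were higher: miR-6751-3p, miR-17-5p, miR-20b-5p, miR-200b-3p, miR-222a-3p, miR-31-5p and miR-125b-5p.

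The second comparison asked which miRNAs had a straight-line slope with day over all 7 libraries. A slope does not show that a change was steady. miR-146b-5p and miR-23b-3p fell and 1 non-conserved entry, named in the key of the plot of RPM by day, rose. miR-146b-5p fell from 2663 ± 1359.9 RPM at day 1 to 420.1 RPM at day 10, 106 at day 15 and 31.5 at day 20, after 5162 RPM at day 5 (log2 change per day -0.34, SE 0.08, limma adjusted p = 0.0304). miR-23b-3p, transcribed with miR-27b, stood at 311 ± 115 RPM at day 1, at 1225 and 803 RPM at days 5 and 10, and was listed at 0 at days 15 and 20 (per day -0.47, SE 0.12, limma adjusted p = 0.0304). The entry that rose had 1.29, 0 and 0 RPM at day 1, 0 at day 5 and 601, 444 and 1486 RPM at days 10, 15 and 20 (per day 0.60, SE 0.13, limma adjusted p = 0.0192). Next by p were miR-27b-3p and miR-146c-5p, with slopes of -0.27 and -0.25 per day, and neither passed (limma adjusted p = 0.169 for both). The median slope of all tested miRNAs was -0.12 per day. limma with Benjamini-Hochberg adjustment thus called 3 of 158 miRNAs, against 21 at an unadjusted p under 0.05. It called 1 of 10 tested immune regulators (2 when adjusted over the list alone), 1 of 26 milk miRNAs (1 adjusted over the list alone) and 0 of 6 in lipid metabolism (1 adjusted over the list alone). The smallest adjusted p of camera was 0.304, and it was 0.868 with an estimated correlation.

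The trend calls depended on single libraries and on the settings. With a pseudocount of 10 none of the 3 passed, with no filter the entry that rose alone passed, and with conserved entries only neither miR-146b-5p nor miR-23b-3p did. Without day 20, miR-146b-5p and miR-23b-3p had adjusted p of 0.197 and 0.167, the entry that rose did not pass either, and 2 miRNAs passed instead: miR-215-5p and miR-6834-5p. Without day 15 only the entry that rose passed, with adjusted p of 0.116 for both miR-146b-5p and miR-23b-3p. miR-146b-5p also missed the threshold without day 1 replicate 2 (0.0964) or 3 (0.0757) and with median-of-ratios scaling (0.0589), which called 5 miRNAs. With days 15 and 20 left out none passed, and the slope of miR-23b-3p was 0.19, above 0. Among the 4 later libraries alone, where the median slope was -0.27 (0 with median-of-ratios scaling), limma called 0 miRNAs, with 40 at an unadjusted p under 0.05. The smallest p there was that of miR-146b-5p (slope -0.48 per day, limma adjusted p = 0.109), followed by miR-146c-5p (-0.42), miR-30e-5p (-0.38), miR-27b-3p (-0.44) and miR-30c-5p (-0.35). It called 14 miRNAs without day 5, 6 without day 10, 0 without day 15 and 10 without day 20.

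Each later day was then compared with day 1. At day 5, 4 of 11 tested members of the miR-17-92 clusters, which promote cell proliferation, were higher. miR-20b-5p rose from 47.7 ± 2.58 RPM (SD, n = 3) to 1095 RPM, 22.9-fold (log2 change 4.49, SE 0.15, limma adjusted p = 0.00467). miR-20a-5p rose from 71.6 ± 6.04 to 818 RPM (11.4-fold, log2 change 3.50). miR-17-5p, chosen after its values were seen, rose from 54.9 ± 2.10 to 617 RPM. Of the miR-200 family, which maintains the epithelial state, miR-200b-3p rose from 461 ± 61.1 to 4005 RPM (8.70-fold, log2 change 3.13, SE 0.23). These folds are of RPM, not rescaled for the larger listed share at day 5. As shares of listed reads, the miR-17-92 clusters held 2.73, 3.12 and 3.09% in the day 1 replicates and 4.52% at day 5. The miR-200 family held 3.15, 1.63 and 4.67%, and 5.44% at day 5. The largest log2 changes belonged to miRNAs listed at 0 in every day 1 library: miR-6751-3p (13.45, at least 5804-fold), a non-conserved entry (9.13, at least 290.0-fold) and miR-6325-3p (8.78, at least 228-fold). The latter entries had the same read numbers at day 5 (262 and 206) as another entry each, and whether they are separate miRNAs is uncertain. let-7a-5p was the 1 miRNA that fell, from 295 ± 94.0 RPM to a listed 0 (at least 46.1-fold, log2 change -8.17, limma adjusted p = 0.0120). Its near-identical relative let-7j-5p had 1104 RPM at day 5 against 296 ± 94.6 at day 1, so the fall of let-7a-5p by name is uncertain, and the family and arm summed had a log2 change of 1.09. miR-21-5p (3.90 times day 1, log2 change 1.98, limma adjusted p = 0.0508) and miR-148a-3p (8.14 times, adjusted p = 0.149) did not pass.

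limma called 22 of 158 miRNAs at day 5, 21 higher and 1 lower, and 7 of the 21 were at 0 in every day 1 library. The higher ones included 4 of 11 members of the miR-17-92 clusters (5 adjusted over the list alone), 2 of 5 of the miR-200 family (3 adjusted over the list alone) and 2 of 6 of the miR-30 family (4 adjusted over the list alone; miR-30a-3p 3.48, miR-30e-3p 3.47). These last had nearly equal read numbers in every library (149 and 144 at day 5), so whether they are separate calls is uncertain, which also bears on the tests of this family. In let-7, 1 of 12 was lower (1 adjusted over the list alone), and of 26 milk miRNAs 1 was higher and 1 lower (1 and 1 adjusted over the list alone). Of the remaining lists no member passed, while adjusted over the list alone 1 of 4 other epithelial miRNAs and 1 of 2 neuronal miRNAs did. fry, which tests whether a list moves on balance one way, gave adjusted p of 0.0165 for the miR-17-92 clusters, the miR-30 family and neurons, and 0.0269 for the miR-200 family. No camera call passed (smallest adjusted p 0.0831, and 0.923 with an estimated correlation). In camera the let-7, immune, milk and fibroblast lists lay below the other miRNAs although their medians were above 0. Of the 158 tested miRNAs, 104 had a log2 change above 0 at day 5, a shift that fry does not take out. The day 5 library also had the largest listed share, and the median log2 change of all tested miRNAs was 1.33, against -0.37 with median-of-ratios scaling and -0.25 with listed-read scaling. The miR-200 family's median of 1.72 as deposited turned to -0.29 and -0.03 under those scalings. They called 10 and 8 miRNAs, 9 and 7 of them higher, with 1 and 0 in the miR-17-92 clusters. Without day 1 replicate 2 there were 10 calls, all higher, and without replicate 3 there were 0.

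At day 10, 2 of 3 tested members of the gut list were higher. miR-215-5p and miR-194-5p are typical of the intestinal epithelium. miR-215-5p rose from 14.0 ± 4.38 RPM to 783 RPM (55.8-fold, log2 change 5.74, SE 0.45, limma adjusted p = 0.0302). miR-194-5p rose from 1.29, 0.713 and 0 RPM to 112 RPM (log2 change 6.17, limma adjusted p = 0.0440), and miR-375-3p, known from endocrine cells, had 184 RPM against 23.4 ± 12.1 and did not pass. In the miR-200 family, miR-200a-5p rose from 12.4 ± 2.41 to 204 RPM (16.5-fold, log2 change 3.96) and miR-200b-3p from 461 ± 61.1 to 4408 RPM (9.57-fold, 3.26). miR-128-3p, of the neuronal list, rose from 25.9 ± 7.25 to 486 RPM (4.21). The largest log2 changes were those of miRNAs listed at 0 in every day 1 library: miR-6834-5p (3312 RPM, at least 1717-fold), miR-6751-3p (624 RPM, at least 324-fold) and a non-conserved entry (549.6 RPM, at least 285-fold).

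limma called 15 of 158 miRNAs at day 10, all higher, and 4 were at 0 in every day 1 library. They included 2 of 3 members of the gut list (3 adjusted over the list alone), 3 of 5 of the miR-200 family (3 adjusted over the list alone), 2 of 11 of the miR-17-92 clusters (5 adjusted over the list alone; their median of 1.46 turned to -0.06 with median-of-ratios scaling), 1 of 2 neuronal miRNAs (1 adjusted over the list alone) and 1 of 26 milk miRNAs (0 adjusted over the list alone). let-7, miR-30 and other epithelial miRNAs had no member past the threshold, and 4, 2 and 1 when adjusted over the list alone. fry passed for the miR-200, miR-17-92, miR-30, neuronal and gut lists, and no camera call did. The median log2 change of all tested miRNAs was 0.91, against -0.22 with median-of-ratios scaling and 0 with listed-read scaling. The median of the miR-200 family was 2.76, 1.22 and 1.72 on these scales. Median-of-ratios scaling called 6 miRNAs, 1 of them lower (miR-21-5p, log2 change -2.10, limma adjusted p = 0.0428) and 1 in the gut list; listed-read scaling called 4, none in the gut list, the miR-200 family or the miR-17-92 clusters. Without day 1 replicate 1, 2 or 3 there were 6, 4 and 0 calls.

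At day 15, miR-215-5p rose to 6498 RPM (463-fold over day 1, log2 change 8.80, SE 0.45, limma adjusted p = 0.00817); its difference from day 10 was not tested. miR-194-5p rose to 651 RPM (log2 change 8.69). In the other direction, the miR-17-92 members miR-20a-5p and miR-20b-5p fell to a listed 0, at least 4.73- and 3.15-fold below day 1. miR-21-5p fell 5.90-fold to 1549 RPM (log2 change -2.55, limma adjusted p = 0.0247) and miR-26a-5p 4.64-fold to 777 RPM. By log2(RPM + 1), the largest falls were those of miR-23b-3p (at least 20.5-fold, log2 change -8.22), miR-365-3p (at least 5.49-fold, -6.24) and miR-20a-5p (-6.18). All were listed at 0, so the pseudocount sets these log2 changes and the depth shows only the bounds. The largest rises were those of a non-conserved entry (11.23, 528 reads), miR-7669-5p (11.22, 524 reads) and miR-8107-1-5p (11.22, 524 reads), each with 1 read in day 1 replicate 2 and none in the other day 1 libraries. These 3 and another non-conserved entry (528 reads) had nearly equal read numbers in this library, and whether they are separate miRNAs is uncertain.

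limma called 31 of 158 miRNAs at day 15, 13 higher and 18 lower. Of the 13, 6 were at 0 in every day 1 library, and of the 18, 13 were listed at 0 at day 15. For 4 of the 18 the day 1 mean also lay under the day 15 floor of 15.1 RPM, so a fall could not be shown at this depth. In the miR-17-92 clusters 5 of 11 were called lower (6 adjusted over the list alone), 1 of them (miR-18b-5p, 14.6 ± 4.04 RPM at day 1) under that floor, and in the gut list 2 of 3 were higher (2 adjusted over the list alone). For both lists camera gave an adjusted p of 0.0257, and 0.819 with an estimated correlation, while fry gave an adjusted p of 0.0334. In let-7 1 of 12 was called (miR-98-5p, 0 adjusted over the list alone), with 8.49 ± 2.43 RPM at day 1, under the floor, so no fall is shown. In miR-10/99/100 1 of 7 was lower (miR-99a-5p, 1 adjusted over the list alone), among immune regulators 1 of 10 (miR-21-5p, 1 adjusted over the list alone) and among milk miRNAs 3 of 26 (3 adjusted over the list alone). No member of the miR-200 family passed, and its median was -0.50, 1.03 with median-of-ratios scaling and 0.09 with listed-read scaling. The median log2 change of all tested miRNAs was -1.70, against -0.71 and -1.66 on these scales. With a pseudocount of 10 it was -0.95. Median-of-ratios scaling called 14 higher and 10 lower, and listed-read scaling 11 higher and 23 lower, with 4 and 5 lower in the miR-17-92 clusters. With no filter there were 29 higher and 16 lower, and with a pseudocount of 10 there were 13 higher and 8 lower. Without day 1 replicate 2 there were 11 higher and 5 lower, and without replicate 3 there were 8 higher and 4 lower, so the balance turned.

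At day 20, 3 of the 10 most abundant entries of day 1 were lower and the others did not pass. miR-21-5p fell 12.1-fold to 755 RPM (log2 change -3.58, SE 0.25, limma adjusted p = 0.0137) and miR-26a-5p 13.2-fold to 273 RPM (adjusted p = 0.0137, and 0.0572 with median-of-ratios scaling). miR-146b-5p fell 84.6-fold to 31.5 RPM (log2 change -6.19, limma adjusted p = 0.0465, and 0.157 with median-of-ratios scaling). miR-148a-3p, miR-10a-5p, miR-27b-3p, miR-146c-5p and miR-205a-5p had limma adjusted p of 0.0791, 0.0644, 0.0586, 0.109 and 0.627. miR-215-5p fell to a listed 0 (at least 1.34-fold, limma adjusted p = 0.0307). miR-30e-5p fell 15.1-fold to 55.9 RPM. These folds are of RPM, not rescaled for the smaller listed share at day 20. miR-21-5p held 216 of the 3620 listed reads there. In the day 1 replicates it held 14385 of 82000, 29455 of 171825 and 31652 of 156600. miR-200b-5p fell from 21.1 ± 1.17 RPM to a listed 0 (at least 2.01-fold), and miR-20a-5p from 71.6 ± 6.04 RPM to 1 read. By log2(RPM + 1), the largest falls were those of miR-23b-3p (at least 29.6-fold, log2 change -8.22), let-7j-5p (at least 28.2-fold, -8.17) and miR-146b-5p. For miR-23b-3p and let-7j-5p, listed at 0, the pseudocount sets the log2 change, while the 84.6-fold fall of miR-146b-5p is a measured ratio. The order is therefore uncertain. The fall of let-7j-5p by name is uncertain, because let-7a-5p kept 15 reads in this library. The largest rises were those of 2 non-conserved entries (10.14, and 9.65 or at least 415-fold) and miR-4260-1-5p (9.54). The second entry and miR-4260-1-5p both had 229 reads in this library, and whether they are separate miRNAs is uncertain.

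limma called 39 of 158 miRNAs at day 20, 11 higher and 28 lower. Of the 11, 7 were at 0 in every day 1 library, and of the 28, 14 were listed at 0 at day 20; for 1 of the 28 the day 1 mean lay under the day 20 floor of 10.5 RPM. Lower members were 6 of 11 in the miR-17-92 clusters (6 adjusted over the list alone), 2 of 5 in miR-200 (3 adjusted over the list alone), 2 of 12 in let-7 (2 adjusted over the list alone), 1 of 6 in miR-30 (1 adjusted over the list alone) and 1 of 7 in miR-10/99/100 (4 adjusted over the list alone). Lower members were also 2 of 10 immune regulators (1 adjusted over the list alone), 2 of 6 in lipid metabolism (miR-103-3p -3.16 and miR-130a-3p -2.97; 5 adjusted over the list alone), 5 of 26 milk miRNAs (4 adjusted over the list alone) and 1 of 3 in the gut list (1 adjusted over the list alone). No camera call passed, and fry passed for 5 lists: miR-17-92, miR-200, miR-30, miR-10/99/100 and milk. In the lipid metabolism list, miR-103-3p and miR-130a-3p had 2 reads and 1 read at day 20, under the floor of 10.5 RPM. For these members the depth shows only smaller falls than their log2 changes. The median log2 change of all tested miRNAs was -2.43, against -1.29 with median-of-ratios scaling and -1.72 with listed-read scaling. With a pseudocount of 10 it was -1.24. Of the 158 tested miRNAs, 134 had a log2 change below 0, a shift that fry does not take out. The direction of the miR-30 family turned with median-of-ratios scaling, from a median of -2.13 to 0.13, and that of miR-17-5p from -1.13 to 1.11. Median-of-ratios scaling called 13 higher and 15 lower, and listed-read scaling 8 higher and 24 lower. Lipid metabolism had 0 and 1 lower members on these scales. With no filter there were 21 higher and 22 lower, and with a mean of at least 100 reads 2 higher and 22 lower. Without day 1 replicate 2 the balance turned, to 8 higher and 3 lower, and without replicate 3 there were 0 calls.

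**Figure D3:**
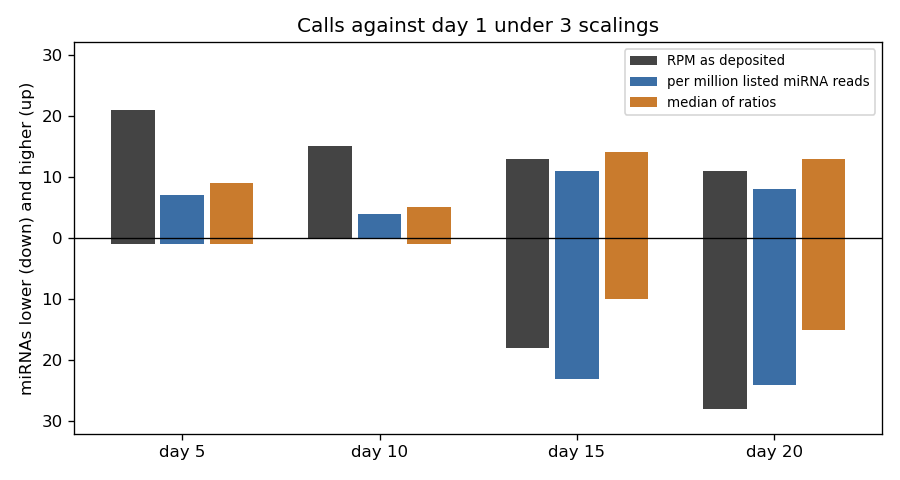
Number of miRNAs past an adjusted p of 0.05 (limma) at each later day against day 1, higher upward and lower downward, with RPM as deposited, with listed-read scaling and with median-of-ratios scaling. As deposited 21 were higher and 1 lower at day 5, and 11 higher and 28 lower at day 20; with median-of-ratios scaling these were 9 and 1, and 13 and 15.

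The fixed lists of other cell types asked which sources the milk RNA could hold. No tested member of the lists of red blood cells (3 tested), leukocytes (2), muscle (1), endothelium (1), fibroblasts and matrix (4) or other epithelial miRNAs (4) passed in any comparison as deposited. The liver list had 0 entries, and the hypoxia list had 2 entries that were too rare to test. The hypoxia miRNA miR-210-3p had between 0 and 12.8 RPM. Of the red blood cell list, miR-16-5p had 381, 57.0 and 110.4 RPM at day 1 and 544, 771, 116 and 62.9 RPM at the later days. miR-15a-5p had between 6.99 and 83.4 RPM. Of the other epithelial list, miR-31-5p had 57.9 ± 21.1 RPM at day 1 and 728, 924, 80.7 and 17.5 RPM at the later days. The gut list held 21.7% of listed reads at day 15 and 1.05% at day 10, against 0.0866, 0.0402 and 0.116% in the day 1 replicates, 0.0374% at day 5 and 0.0552% at day 20. At day 15 miR-215-5p gave 1288 of the 1422 reads of this list. Day 1 replicate 1 stood apart from replicates 2 and 3. The muscle miRNA miR-133a-3p had 92.6 RPM there against 0.713 and 0, the endothelial miR-126-5p 62.4 against 0.356 and 0.484, and miR-143-3p, typical of smooth muscle and fibroblasts, 227 against 0 and 0. The matrix regulator miR-29c-3p had 129 RPM against 18.9 and 7.99. The leukocyte miRNA miR-142-5p had 250.1 RPM against 29.6 and 21.1.

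The composition of the libraries was compared over 9 measures. Between 168 and 203 miRNAs had a read in the day 1 libraries, and 156, 156, 119 and 95 at days 5, 10, 15 and 20, a difference of means of -54.8. It had an exact permutation p of 0.0857, where the smallest possible was 0.0286, and no measure differed between day 1 and later days after adjustment (smallest adjusted p 0.771). With day, the number had r = -0.95 and rho = -0.95 (exact permutation p = 0.00238 and adjusted p = 0.0214 for both), and r = -0.72 without days 15 and 20; 3 of the 7 points share day 1. After thinning to a common denominator the relation did not pass (r = -0.58, rho = -0.30, exact permutation p = 0.18 for r). The non-conserved entries held 5.74, 11.5 and 0.154% of listed reads at day 1, 0.528 and 1.5% at days 5 and 10, and 30.4 and 29.2% at days 15 and 20 (r = 0.78, exact permutation p = 0.0440, adjusted p = 0.198; rho = 0.56, p = 0.212). That relation did not pass and rested on days 15 and 20, without which r was -0.46. At day 15 the share included non-conserved entries with the same read number (528), and whether they are separate miRNAs is uncertain. The 5p arms held 76.9, 65.5 and 69.2% at day 1, 56.2 and 47.5% at days 5 and 10, and 85.1 and 63.4% at days 15 and 20. These shares depend on the arm under which miR-22 was entered, which is taken up in the closing section. Its reads stood on 5p in day 1 replicate 1 and at day 5 (2922 and 1897 reads). In the other libraries they stood almost wholly on 3p (4309 reads at day 10). The most abundant miRNA held between 13.2 and 20.3% of listed reads, and the let-7 family between 1.19 and 6.99%. At day 10 let-7a-5p and let-7j-5p each had 652 of the 2484 let-7 reads. At day 5 they had 0 and 517 reads, and at day 20 they had 15 and 0. Whether the let-7 share counts some reads more than once in some libraries is uncertain.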

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

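Of the settings below, scaling to equal listed totals, both thinned settings, summing both arms, keeping conserved entries only, keeping entries with identical values once, leaving out days 15 and 20, and leaving out a library in the composition measures were added after the data were seen; equal listed totals was added after the results of listed-read scaling were known. edgeR with TMM, DESeq2 and limma-voom were left out, because each library had fewer than the 100 low values set as the minimum for treating its reads as recovered. No paired analysis was possible because the labels link no library of one day to a library of another. Over 55 named results 689 values kept their direction and their side of the threshold, 26 passed newly, 147 no longer passed and 3 reversed; over 96 counts of list members 556 values stayed within 1.5 times and 136 did not. Among the counts of calls, the total under every other alternative run and not named below stayed within 1.5 times, although the balance of higher and lower calls could change (no filter at day 15, 29 higher and 16 lower; thinning at day 15, 12 and 10).

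For days 5 to 20 against day 1 (1 call), a mean of at least 100 reads gave 0, a pseudocount of 10 gave 0, and thinning with a pseudocount of 10 gave 0; days 15 and 20 left out gave 7, and leaving out a library 1 to 2. For the trend (3), median-of-ratios scaling gave 5, equal listed totals 6, no filter 1, at least 100 reads 5, a pseudocount of 10 gave 0, thinning 5, conserved entries only 0, days 15 and 20 left out 0, and leaving out a library 1 to 3. For the trend among days 5 to 20 (0), at least 100 reads gave 5, thinning 3, thinning with a pseudocount of 10 also 3, and leaving out a library 0 to 14. At day 5 (22), median-of-ratios scaling gave 10, listed-read scaling 8, equal listed totals 9, at least 100 reads 9, and leaving out a library 0 to 32. At day 10 (15) these scalings gave 6, 4 and 4, a pseudocount of 10 gave 26, and leaving out a library 0 to 6. At day 15 (31), at least 100 reads gave 12, thinning with a pseudocount of 10 gave 18, and leaving out a library 12 to 34. At day 20 (39), equal listed totals gave 25, at least 100 reads 24, thinning 20, thinning with a pseudocount of 10 gave 19, and leaving out a library 0 to 33. With a mean of at least 100 reads fewer miRNAs are tested; for the other changes the cause was not tested.

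Among the 55 named results, reversed values were the trend of miR-23b-3p (0.19 per day) and of miR-148a-3p (0.25) with days 15 and 20 left out, and let-7a-5p at day 5 (1.09 with family and arm summed). Values outside these also turned with median-of-ratios scaling, such as miR-17-5p and the miR-30 median at day 20 and the miR-200 median at day 5. In composition, the later minus day 1 difference in the listed share was 3.07 percentage points and -0.13 to 5.35 when a library was left out. The difference in composition: miRNAs with a read after thinning, days 5 to 20 minus day 1, was -6.83, with -19 (without day 1 replicate 3) to 5 (without day 20) when a library was left out, and 0 without day 1 replicate 2. For the share of the most abundant miRNA it was -1.65, and 3.00 without that miRNA; for entropy it was 0.17, with -0.0387 to 0.410 when a library was left out. For let-7, where let-7a-5p and let-7j-5p may share reads, it was 0.203, and -0.114 without the most abundant miRNA. It was -1.20 to 1.06 when a library was left out. The cause of these was not tested. Depth limits days 15 and 20, where the floor was 15.1 and 10.5 RPM.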

Other observations

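All tests in this part were chosen after the results they bear on had been seen, as were let-7f-5p, miR-2954-3p and miR-22-5p.

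Many entries belonged to 1 library. Of the 301 entries, 99 had at least 95% of their summed RPM in a single library; 74 of the 99 had at least 10 reads there, and 38 of the 99 were non-conserved. Those belonging to the library itself held 39.4% of its listed reads at day 15 (19 entries) and 21.3% at day 20 (12 entries), against 11.4, 11.3 and 0.172% in the day 1 replicates (23, 21 and 8 entries) and 0.524 and 0.537% at days 5 and 10 (9 and 7 entries). At days 15 and 20 these shares rested on 2584 and 771 reads. Entries with 524, 524, 528 and 528 reads at day 15, and with 229 and 229 at day 20, may not be separate miRNAs. If they are not, reads could have been counted more than once in the shares of those days. let-7f-5p had 521 RPM in day 1 replicate 1 against 5.70 and 0.484 in the others. miR-2954-3p, an avian miRNA of the Z chromosome that is more abundant in males, had 107, 185 and 8.23 RPM at day 1, 961 at day 5, 285 at day 10, 0 at day 15 and 97.9 at day 20. The labels do not give the sex of the parents.

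Immune regulators held 23.1, 34.0 and 36.3% of listed reads in the day 1 replicates, 27.6% at day 5, 8.44% at day 10, 6.69% at day 15 and 7.43% at day 20. The lipid metabolism list held 6.14, 13.5 and 16.3% at day 1, 21.9% at day 5, 14.8% at day 10, 1.69% at day 15 and 2.32% at day 20. Both are shares without a test between days. Each rested largely on a single member that is also in the milk list. At day 5 miR-21-5p gave 16695 of the 22877 reads of the immune list. miR-148a-3p gave 16807 of the 18154 reads of the lipid metabolism list there. At day 10 these were 2126 of 3002 and 4788 of 5246 reads. The shares therefore do not show a whole list moving.

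RPM was higher at day 5 and lower at day 20 than at day 1 for most miRNAs. At day 20, unequal depth did not account for the whole shift, since the median log2 change was -1.65 after thinning with a pseudocount of 10 and -2.52 in another version. With equal listed totals the median was -0.17 at day 5 (quartiles -1.78 to 0.75), where 1.33 stood as deposited, and -1.54 at day 20 (quartiles -3.25 to 0.36), where -2.43 stood; among 32 to 39 entries with a read in at least 4 libraries, thinned to equal listed reads, it was 0.13 and -0.67. The listed share is the sum of the same RPM values, so equal totals take out a general shift whatever its cause, and a larger listed share at day 5 stays open; so does a smaller one at day 20, where -1.54 alone would argue against it as the whole cause but the rule that both versions must point one way was set after their values were known. Why the listed share differed was not tested, and the stage itself stays open for both days as a biological explanation.

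In day 1 replicate 1 and at day 5, miR-22-3p was listed at 0 while miR-22-5p had 2922 and 1897 reads, and miR-22-5p had 8 and 8 reads in day 1 replicates 2 and 3. Reads of one arm entered under the other name may explain this: both arms summed in replicate 1 differed from replicates 2 and 3 by 0.74 log2 units, against 10.13 for miR-22-3p alone. In all, 6 of 53 hairpins had at least 90% of reads on opposite arms in different libraries. No sequence was read to decide it, and a change of arm in the milk stays open.

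Some entries had nearly equal read numbers within 1 library, such as the 3 largest rises at day 15 with 528, 524 and 524 reads. Reads of one sequence listed under several names could give this: 51 of 7719 pairs with at least 100 reads differed by at most 1%, against a mean of 37.9 and a highest of 58 in 1000 sets with jittered values, which leaves it undecided. Another version compared 89 entries with at least 20 reads in at least 3 libraries, so it could not see pairs of a single library. It found 1 pair within 2% in every library with 20 reads (miR-29a-3p and miR-29c-3p), against 0 in each of 100 sets. Some pairs in single libraries were exactly equal, such as 2139 reads each in day 1 replicate 1. Keeping entries with identical values in all libraries once lowered the tested entries from 158 to 156. let-7a-5p and let-7j-5p differed by at most 3 reads in the 5 libraries that had both, and at day 5 let-7j-5p alone was listed, with 0.623% of listed reads. No biological explanation was tested.

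For days 5 to 20 against day 1, 11 of the 35 splits of the libraries gave at least 1 call, so chance cannot be excluded (real value 1, highest other 1). For the trend, 5 of 100 assignments of days to libraries gave at least 3 calls, so chance cannot be excluded (real value 3, highest other 22). An assignment with 22 calls gave several times the real count, and the reason was not tested. The 3 assignments with the most calls (22, 12 and 6) had days with r = -0.87, -0.82 and -0.74 against the log of the listed share, while others with r = -0.74 and 0.76 gave 1 and 0 calls; this relation over assignments was not tested.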
